A study of Mus musculus with 12 samples.

How the data were processed

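Per the labels, the series holds 12 mouse RNA-seq libraries from sorted lung cells of animals on the C57Bl/6 background. Per the labels, the animals had spent 3 weeks in hypoxia with weekly SU5416, and interstitial macrophages (IM) and nonclassical monocytes (NCM), about 250 cells per library, were sorted from animals with Cx3cr1-driven Cre and deleted Hif1a or from Cre-negative animals with floxed Hif1a. Each of the 4 groups has 3 libraries. Per the labels, libraries were made with a stranded total RNA kit for low input, which keeps unspliced and nuclear RNA in the sample. Per the submitters' processing notes, cutadapt 1.12, TopHat2 2.1.1 and HTSeq 0.6.0 were used with the genome build GRCm38 (mm10). The role and options of each tool, the gene annotation, the strand setting and the handling of reads that align to several places are not given in the sources used here.

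The deposited files hold raw counts of reads per gene, 1 file per library, as whole numbers that the authors had neither normalized nor filtered. Each file has 26608 gene rows, named by symbol, and 5 summary rows for reads in no gene row. The summary rows took between 45.0 and 74.1% of the reads of a library, which comprise reads outside annotated exons, reads that aligned to several places (4.44 to 9.02%) and reads that overlapped several genes (0.560 to 1.78%). Depth was between 5332600 and 14099509 gene counts per library. The share of non-exonic reads is given as a percentage of gene counts plus non-exonic reads. The lane of each library was taken from the names of the deposited files. Lanes 5 and 7 held IM and lanes 6 and 8 held NCM libraries, so lane and cell type cannot be separated, and both genotypes share lanes within a cell type.

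Gene symbols were matched to the RefSeq table of GRCm38.p6 (24587 rows matched) and to GENCODE M21 (24512 rows with a single gene), from which coordinates and exon lengths were taken. Symbols are printed as the files give them. The annotation the authors counted with is not known, so a symbol may cover other exons than the matched gene.

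Computations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9 for figures. Genes were kept by edgeR's filterByExpr by group with its minimum count of 10, which left 14254 genes. Library sizes were scaled with TMM factors, and all 12 libraries entered a single robust quasi-likelihood fit with 4 group means. Contrasts were IM deleted against IM control, NCM deleted against NCM control, the difference of these 2 effects, IM control against NCM control and IM deleted against NCM deleted. A gene passed when its Benjamini-Hochberg adjusted p was under 0.05. Levels are mean CPM ± SD of the libraries of a group, with library sizes multiplied by their TMM factors, while fold changes come from the fit, so the ratio of 2 levels can differ from the fold. A floxed gene can be counted at its normal level when only some exons are lost, and reads per exon were not analysed here.

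The gene lists numbered 24, with 568 entries of which 556 are in the files. They cover glycolysis, other hypoxia response genes, oxidative phosphorylation, inflammatory cytokines and NF-kB, interferon response, alternative activation and repair, factors that act on vessels, MHC class II, cell cycle, immediate early and stress genes, sex-linked genes and nuclear RNAs. The others hold markers of interstitial and alveolar macrophages, nonclassical and classical monocytes, dendritic, T and NK, B, endothelial, epithelial, fibroblast and smooth muscle, erythroid and platelet cells and neutrophils. They were tested with camera on voom log2 CPM with its preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison, and, as alternatives, with an estimated correlation and with fry. Each list's members were counted as past the threshold over all genes and, separately, with p-values adjusted over the list alone. Where all libraries of a group had no count of a member, no fold is given, and the list median was also computed with that group at a floor of 3 counts. List medians were set beside those of 10000 random lists matched in 10 bins of expression and 5 bins of exon length. Intervals of medians are 95% percentile intervals from 10000 bootstrap draws of the list's genes, so they cover the spread between genes and leave out the spread between libraries.

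Genes are named by a fixed rule. Gene models with systematic names, pseudogenes, mitochondrial and ribosomal RNA and small RNAs were passed over. Among genes with a mean log2 CPM of at least 4 over the 6 libraries compared, an adjusted p under 0.05 and no overlap between the libraries of the 2 groups, the 10 with the largest fold change in each direction are named (5 per direction for the difference of effects, without the overlap condition). A direction with fewer was filled with the smallest unadjusted p, and those genes are described as not past the threshold. Hif1a, Cx3cr1 and up to 4 members of each list past the threshold, or up to 2 given as values where none passed, complete the set, of which the text prints a part. Groups, comparisons, tests, lists, the naming rule and most alternatives were fixed before the data were examined.

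The procedure was tested on simulated data with the depths, dispersions and group sizes of these libraries. Of 100 genes changed 4-fold, 44% were recovered in IM, 52% in NCM, 13% in the difference of effects, 46% between the control groups and 48% between the deleted groups. Of 100 genes changed 2-fold, 0%, 3%, 1%, 5% and 6% were recovered. Between 1 and 4 unchanged genes were called per contrast. Camera recovered a glycolysis list changed 2-fold in each contrast and called 0 of the 23 other lists. Simulated genes were drawn independently, so this does not show how camera behaves when genes are correlated. Among other splits of the real IM libraries, the highest gave 16 lists.

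Alternatives were DESeq2, RLE factors, no low-count filter, a minimum count of 30, a fit of only the libraries compared, and limma-voom with sample weights, which changes test and weights together. Others were removal of 19 rows of ribosomal RNA, mitochondrial, haemoglobin and sex-linked genes, thinning to the depth of the shallowest library, leaving out each library, lane as a covariate, and the number in the titles as a block. The block was random in a limma-voom fit for the genotype effects and fixed in an edgeR fit for the comparisons of cell types, so for the former tool and block changed together. Chosen after the data had been seen were scaling by total counts, the share of non-exonic reads as a covariate, cyclic loess before limma-voom, the matched random lists and the genotype effect averaged over both cell types. Other splits of the libraries into groups were run as well, 10 for each comparison of 3 against 3 libraries and 100 for the contrasts over both cell types. Strand-specific, splice-level and sequence-level results were not analysed here, because only counts per gene were held.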

Results

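RNA was sequenced from small pools of sorted mouse lung cells, about 250 cells per library, to compare animals whose labels give a deletion of Hif1a in Cx3cr1-expressing cells with control animals. Hif1a encodes the oxygen-regulated subunit of the transcription factor HIF-1, and Cx3cr1 encodes a chemokine receptor of monocytes and macrophages. Per the labels, the deleted animals carried a Cre recombinase under Cx3cr1 to excise floxed Hif1a, whereas the controls carried the floxed alleles without Cre. The counts do not measure the excision. All animals had been kept in hypoxia for 3 weeks, with SU5416, an inhibitor of VEGF receptors, given every week. This exposure is used to produce pulmonary hypertension in rodents. Interstitial macrophages (IM), the macrophages of the lung tissue outside the airspaces, and nonclassical monocytes (NCM), which patrol the vessel wall, were sorted from the lungs. The 12 libraries thus formed 4 groups of 3, called here IM control, IM deleted, NCM control and NCM deleted, and each library is named here by its cell type and its number in the labels. Only deleted animals carried Cre, so the driver and the deletion cannot be told apart. The labels do not say that the numbers stand for separate animals, so p-values measure spread pooled over all 12 libraries, which may be technical.

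The gene counts summed to 14099509, 13763234 and 13333039 in the IM control libraries IM648, IM659 and IM660, and to 7432617, 7039631 and 9054232 in the IM deleted libraries IM649, IM650 and IM661. They summed to 7238612, 8583265 and 8338488 in the NCM control libraries NCM648, NCM657 and NCM659, and to 5332600, 6109857 and 11169706 in the NCM deleted libraries NCM649, NCM650 and NCM661. Between 10526 genes (NCM649) and 17179 genes (NCM661) had a count. Correlations of log2 CPM (counts scaled to the library size after TMM) between libraries of a group lay between 0.890 and 0.928 in IM control, 0.866 and 0.919 in IM deleted, 0.837 and 0.881 in NCM control and 0.740 and 0.809 in NCM deleted. The first principal component held 34.2% of the variance and placed the IM libraries between -79.14 and -67.99 and the NCM libraries between -26.12 and 225.5. NCM661 lay nearest to the IM libraries and NCM649 farthest from them.

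The share of reads that aligned outside annotated exons differed between the groups. As a percentage of exonic and non-exonic reads it was 42.0 ± 3.06% (SD, n = 3) in IM control and 65.2 ± 5.48% in IM deleted, with no overlap between the libraries of the 2 groups (38.5 to 44.2% against 59.2 to 69.8%). It was 61.7 ± 4.54% in NCM control and 66.6 ± 9.91% in NCM deleted. An exact two-sided permutation test gave p = 0.1 for IM, the smallest value that 3 against 3 libraries allow, and p = 0.4 for NCM. Malat1, a long RNA retained in the nucleus, took 1.35 ± 0.435% of the gene counts in IM control, 4.42 ± 0.132% in IM deleted, 2.83 ± 0.856% in NCM control and 4.01 ± 0.480% in NCM deleted.

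Levels below are mean CPM ± SD over n = 3 libraries per group, with the deleted group first unless stated. Changes were tested with edgeR's quasi-likelihood test over 14254 genes, and its Benjamini-Hochberg adjusted p is given. The genes named as the largest changes between 2 groups passed this test with no overlap between the libraries of the groups. Gene lists were tested with camera.

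The targeted gene, Hif1a (GRCm38 chromosome 12, 73901375 to 73947530), was counted in every library. Its level in IM648, IM659 and IM660 was 230.7, 212 and 243 CPM, and in IM649, IM650 and IM661 it was 192, 204 and 200.01 CPM. In NCM648, NCM657 and NCM659 it was 246, 221 and 207 CPM, and in NCM649, NCM650 and NCM661 it was 154, 212 and 150.3 CPM. The group levels were 199 ± 6.50 against 228 ± 15.6 CPM in IM (log2 fold change -0.20, adjusted p = 0.938). In NCM they were 172 ± 34.8 against 225 ± 19.6 CPM (log2 fold change -0.38, adjusted p = 0.407). Neither difference passed the test. The counts cover the whole gene, and the labels do not name the floxed part. A transcript that lacks only the excised part would still be counted, so these values do not measure the efficiency of the deletion.

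Cx3cr1 (chromosome 9, 119901616 to 120069879) is the gene whose regulatory sequence drives Cre in the deleted animals. It stood at 199 ± 85.4 against 392 ± 66.2 CPM in IM (log2 fold change -0.98, adjusted p = 0.448) and at 123 ± 75.7 against 219 ± 72.7 CPM in NCM (-0.84, adjusted p = 0.356). All 3 IM deleted libraries (129, 174 and 295 CPM) lay below the 3 IM control libraries (316 to 433 CPM), whereas the NCM groups overlapped.

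**Figure D1:**
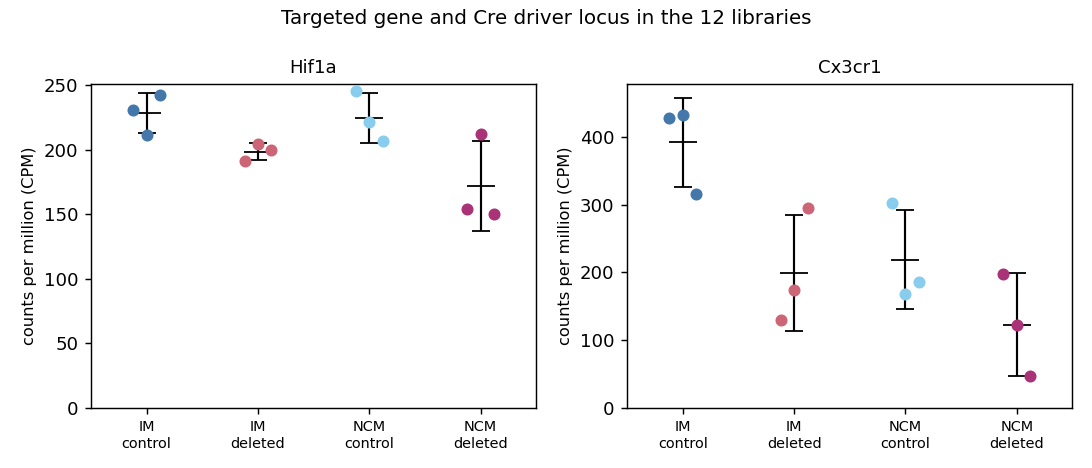
Level of Hif1a and Cx3cr1 in CPM (vertical axis, starting at 0) in the 4 groups; each point is 1 library and the bar and whiskers give the mean ± SD of 3 libraries. Hif1a lies between 150.3 and 246 CPM in all 12 libraries, and Cx3cr1 is 199 ± 85.4 CPM in IM deleted against 392 ± 66.2 CPM in IM control.

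Comparison of NCM deleted with NCM control asks how nonclassical monocytes of the hypoxic lung differ when Hif1a has been deleted. In NCM deleted, inflammatory cytokine and chemokine genes were lower. Tnf, which encodes the cytokine TNF (chromosome 17, 35199381 to 35202007), fell 8.53-fold (12.3 ± 3.98 against 104 ± 13.1 CPM, adjusted p = 0.000788). C5ar1, the receptor for the complement fragment C5a (chromosome 7, 16246743 to 16259540), fell 8.13-fold (14.3 ± 3.28 against 116 ± 21.2 CPM, adjusted p = 8.28e-05). The chemokine gene Ccl4 fell from 65.1 ± 5.62 to 3.26 ± 3.94 CPM (adjusted p = 0.0395). Cxcl2 (5.69-fold, 27.3 ± 14.2 against 155 ± 82.9 CPM, adjusted p = 0.0439) and Ccl3 (5.18-fold, 28.0 ± 11.2 against 145 ± 17.8 CPM, adjusted p = 0.00624) fell as well. So did Nfkbia, an inhibitor of NF-kB that NF-kB itself induces (3.37-fold, 115 ± 5.63 against 389 ± 49.3 CPM, adjusted p = 0.0260). In the list of inflammatory cytokine and NF-kB genes 5 of 28 measured members fell, none rose and 23 did not pass, and 15 fell when adjusted over the list alone. The list median was -1.25 log2 units (camera adjusted p = 3.83e-06; adjusted p = 0.374 with an estimated correlation). Without NCM661 the list median was -0.89. Ccl4 had a log2 fold change of -4.25, and of -5.95 without NCM661. The number of members that fell was 2 without IM648, IM659 or NCM657, 3 without IM660, IM649, IM650 or NCM649, and 8 without NCM650 or NCM661.

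**Figure D2:**
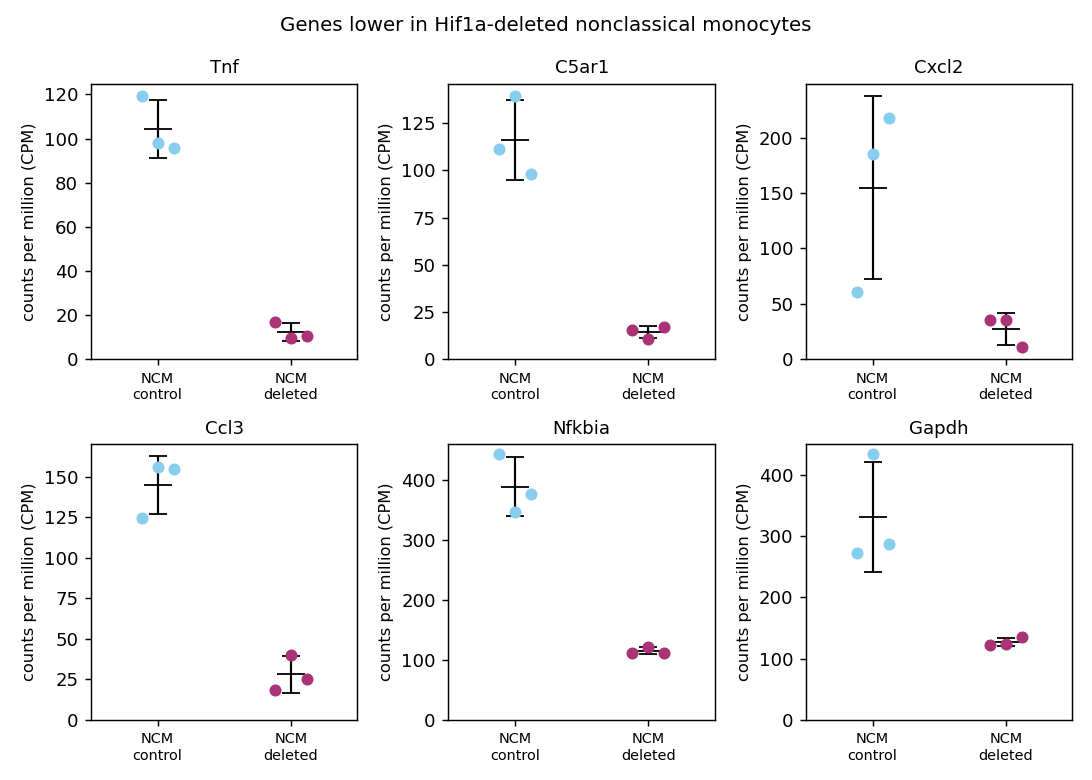
Level in CPM (vertical axis, starting at 0) of 6 genes lower in NCM deleted, in NCM control and NCM deleted; points are libraries and bars with whiskers the mean ± SD of 3. Tnf falls from 104 ± 13.1 to 12.3 ± 3.98 CPM and C5ar1 from 116 ± 21.2 to 14.3 ± 3.28 CPM between NCM control and NCM deleted, with no overlap of the libraries.

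Further genes fell in NCM deleted. They were Gas7 (6.94-fold), Pstpip1, an adaptor of the actin cytoskeleton (5.44-fold, 10.2 ± 2.27 against 55.9 ± 16.8 CPM), and Cmklr1, the receptor for chemerin (4.67-fold). The others were Cd33, a sialic acid-binding lectin (4.44-fold, 8.82 ± 5.74 against 39.7 ± 6.66 CPM), Nfkbid, a nuclear regulator of NF-kB (4.39-fold), and Hexa, a lysosomal hexosaminidase subunit (3.96-fold). Their adjusted p lay between 0.0260 (Gas7) and 0.0472 (Nfkbid). The genes that rose most were Shroom3, an actin regulator of epithelial cell shape (7.74-fold, 97.3 ± 30 against 12.6 ± 6.72 CPM), Hspg2, the basement membrane proteoglycan perlecan (7.44-fold, 293 ± 57.2 against 39.4 ± 21.1 CPM), Nckap5 (6.89-fold) and Dock6 (6.00-fold). Zcchc14 (4.63-fold), Myo10, an unconventional myosin (4.04-fold), and Syne1, a nuclear envelope protein (4.01-fold, 502 ± 154 against 125 ± 13.1 CPM, adjusted p = 0.00582), rose too. They were followed by Ahrr, the repressor of the aryl hydrocarbon receptor (3.92-fold), Slfn5 (3.92-fold) and Arap3 (3.31-fold). Apart from Syne1 their adjusted p lay between 0.0260 (Dock6) and 0.0474 (Nckap5). Without NCM659 the log2 fold change of Nckap5 was 3.46 in place of 2.78.

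Glycolysis genes were lower in NCM deleted. Eno1, which encodes enolase, fell 3.08-fold (108 ± 23.3 against 332 ± 32.9 CPM, adjusted p = 0.0219), and Gapdh fell 2.60-fold (127 ± 6.44 against 332 ± 89.6 CPM, adjusted p = 0.0260). These 2 of 22 members passed the test, 4 did when adjusted over the list alone, and the list median was -0.59 (camera adjusted p = 0.000545; adjusted p = 0.0623 with an estimated correlation; fry adjusted p = 0.000456). In the same libraries nonclassical monocyte markers had a median of -0.85, 32 of 33 below 0, and endothelial markers one of 1.85, with all 19 above 0. No glycolysis gene passed without IM648, IM659 or NCM657, 1 passed without IM660 or IM649, and 4 passed without NCM650. Both genes have processed pseudogenes, so their counts depend on how shared reads were treated and are uncertain. The other hypoxia response genes did not move together: 0 of 33 passed, 2 fell when adjusted over the list alone, and the list median (-0.06) and mean (0.10) differed in sign (adjusted p = 0.566). Among them Hmox1, which encodes heme oxygenase 1, stood at 52.6 ± 19.4 against 152 ± 77.8 CPM (adjusted p = 0.0660) and Bhlhe40 at 215 ± 19.6 against 412 ± 64.9 CPM (adjusted p = 0.0678). Oxidative phosphorylation genes had a median of -0.41 with 36 of 46 members below 0 and none past the test (adjusted p = 0.0536).

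Markers of the sorted cells were lower in NCM deleted, and those of other cells moved both ways. Nonclassical monocyte markers had a median of -0.85, 32 of 33 lay below 0, and 9 fell when adjusted over the list alone (camera adjusted p = 4.98e-12; adjusted p = 0.392 with an estimated correlation). Over all genes 1 of them fell, Cebpb, a transcription factor of these monocytes (3.16-fold, 273 ± 96.7 against 862 ± 156 CPM, adjusted p = 0.0325). Interstitial macrophage markers had a median of -0.97 (-0.98 with 1 member at the floor). None of 37 passed the test, but adjusted over the list alone there were 14 lower and 2 higher (adjusted p = 0.00308; adjusted p = 0.569 with an estimated correlation). Their members Cd14 (49.6 ± 26.7 against 195 ± 96.5 CPM, adjusted p = 0.0502) and Apoe (613 ± 309 against 1699 ± 315 CPM, adjusted p = 0.0559) did not pass. Immediate early and stress genes had a median of -0.63, none passed, and 9 of 28 fell when adjusted over the list alone (adjusted p = 0.00125; adjusted p = 0.569 with an estimated correlation). Among random lists of like expression and exon length the immediate early list lay at the 21.3 percentile. Without NCM659 the calls of both the interstitial macrophage list and the immediate early list ended (adjusted p = 0.0792 each).

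Transcripts of endothelial cells were higher in NCM deleted as a list, with a median of 1.85 and all 19 members above 0. None passed the test alone, and 16 did when adjusted over the list alone (camera adjusted p = 6.25e-16; adjusted p = 0.374 with an estimated correlation). Cdh5, which encodes VE-cadherin, stood at 1460 ± 636 CPM against 355 ± 254 CPM, and Pecam1 at 872 ± 465 against 327 ± 111 CPM. Robo4 stood at 98.1 ± 43.5 against 15.6 ± 12.9 CPM (adjusted p = 0.0606) and Eng at 195 ± 97.8 against 56.5 ± 25.8 CPM (adjusted p = 0.0739). Without NCM661 the median of the list was 1.17.

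**Figure D3:**
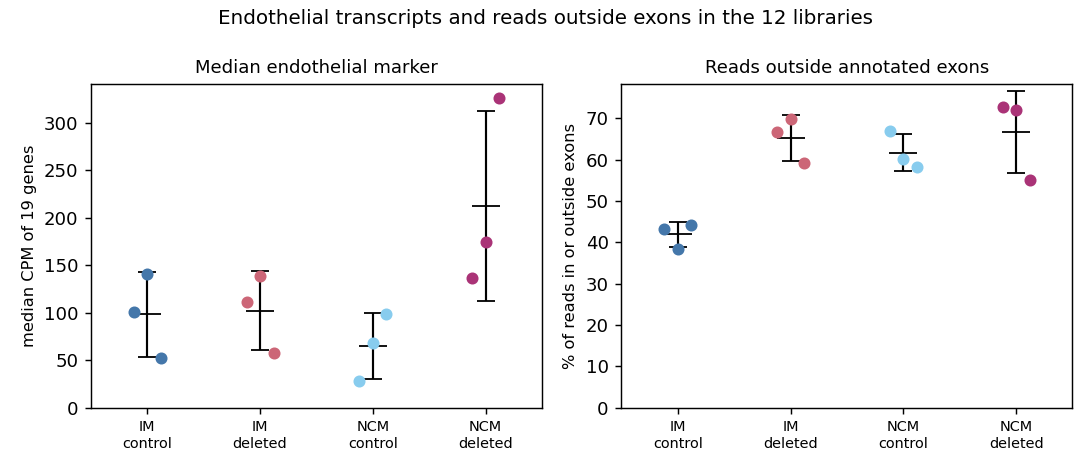
Median level of the 19 endothelial markers in CPM (left) and reads outside annotated exons as a percentage of reads in or outside exons (right) in the 4 groups, with 1 point per library and the mean ± SD of 3. The NCM deleted libraries reach 137, 174 and 326 CPM against 28.5, 67.6 and 98.1 CPM in NCM control, while the right panel separates IM deleted (59.2 to 69.8%) from IM control (38.5 to 44.2%).

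Epithelial markers had a median of 0.91 (adjusted p = 0.000816; adjusted p = 0.569 with an estimated correlation). The only member past the test over the list alone was lower. This was Napsa, an aspartic protease that is also on the nonclassical monocyte list (60.5 ± 21.5 against 172 ± 76.6 CPM, adjusted p = 0.0644 over all genes). Fibroblast and smooth muscle markers had a median of 0.89 with 1 member higher when adjusted over the list alone (adjusted p = 0.00297; adjusted p = 0.569 with an estimated correlation). Col3a1, a fibrillar collagen, stood at 85.9 ± 54.3 against 21.8 ± 4.83 CPM (adjusted p = 0.0827). The epithelial call ended without NCM648 (adjusted p = 0.0582), and the fibroblast call without NCM650 (0.0505) and without NCM661 (0.0555).

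**Figure D4:**
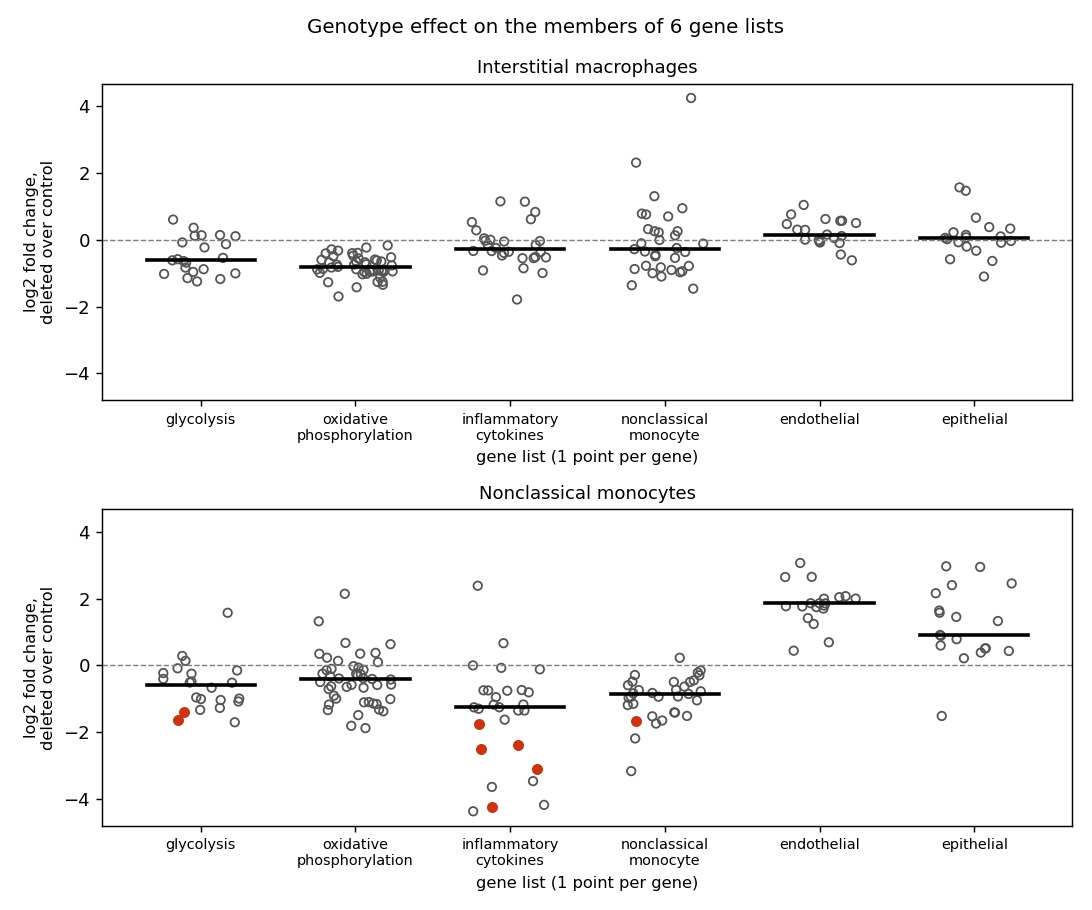
Log2 fold change, deleted over control (vertical axis), of every measured member of 6 gene lists (horizontal axis) in IM (top) and NCM (bottom); open circles did not pass the test, filled red circles did, and the black line is the list median. Inflammatory genes have a median of -1.25 in NCM and -0.29 in IM, and endothelial markers 1.85 in NCM and 0.15 in IM.

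The remaining lists did not pass in NCM. Alternative activation and repair genes had a median of -0.83, -0.87 with 3 members set to the 3-count floor of a group without reads (adjusted p = 0.666). Of them 1 fell, and 4 over the list alone. It was Tgfb1, which encodes the growth factor TGF-beta 1 (2.17-fold, 93.0 ± 11.8 against 202 ± 12.3 CPM, adjusted p = 0.0493). In the list of factors that act on vessels (median -0.32, adjusted p = 0.930) 3 of 38 fell; adjusted over the list alone, 3 rose and 7 fell. They were Tgfb1, Lgals3, which encodes galectin-3 (3.01-fold, 55.9 ± 17.8 against 168 ± 24.5 CPM, adjusted p = 0.0282), and Alox5ap, the activating protein of 5-lipoxygenase (3.95-fold, 19.1 ± 3.71 against 75.5 ± 10.6 CPM, adjusted p = 0.0294). Of the classical monocyte markers (median -0.82, adjusted p = 0.0687) 1 of 16 fell, the chemokine Ccl9 (3.15-fold, 51.2 ± 16.9 against 161 ± 58.0 CPM, adjusted p = 0.0325). Of the interferon response genes (median -0.14, adjusted p = 0.566) 1 of 32 rose, Slfn5. MHC class II genes had a median of -0.79 and a mean of 0.01 (adjusted p = 0.666). Medians were 0.34 for alveolar macrophage markers (adjusted p = 0.328), 0.20 for dendritic cell markers (0.485), -0.48 for T and NK cell markers (0.312) and -0.36 for B cell markers (0.761). They were -0.76 for neutrophil markers (0.312, 2 of 10 lower over the list alone), -0.81 for erythroid and platelet markers (0.761), -0.70 for cell cycle genes (0.157) and 0.45 for nuclear RNAs (0.312, 2 higher over the list alone). For sex-linked genes the median (-0.07) and mean (0.93) differed in sign (adjusted p = 0.981).

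In all, 60 genes passed in NCM, 12 higher and 48 lower, and 8 of the 24 lists, 3 higher and 5 lower. With an estimated correlation 0 lists passed, and 1, glycolysis, passed with fry. That test asks whether the genes of a set move on balance one way and makes no comparison with other genes. With the factors of DESeq2 (RLE) the same test gave 28 higher and 31 lower genes, the median log2 fold change of all genes moving from -0.10 to 0.04. DESeq2 called 953 genes, 603 higher and 350 lower, with all 60 among them, so the larger direction turned. In edgeR 3 genes passed with sequencing lane as a covariate, 0 when only the 6 NCM libraries were fitted, and 351 with the share of non-exonic reads as a covariate. Leaving out 1 library gave 6, 5 and 12 genes (IM648, IM659, IM660), 11, 29 and 91 (IM649, IM650, IM661), 28, 4 and 98 (NCM648, NCM657, NCM659) and 91, 261 and 570 (NCM649, NCM650, NCM661).

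Comparison of IM deleted with IM control asks the same of interstitial macrophages. In IM deleted, long RNAs that stay in the nucleus were higher. Neat1, the scaffold RNA of paraspeckles (chromosome 19, 5824708 to 5845478), rose 7.10-fold (687 ± 488 against 96.8 ± 5.33 CPM, adjusted p = 0.0444). Kcnq1ot1, an imprinted antisense RNA, rose 5.40-fold (703 ± 285 against 130.02 ± 48.3 CPM, adjusted p = 0.0444), and Malat1 rose 3.19-fold (44993 ± 7393 against 14089 ± 4656 CPM, adjusted p = 0.0444). These are the 3 of 9 nuclear RNAs that passed, and 3 when adjusted over the list alone; the list median was 1.68 (camera adjusted p = 0.0401; adjusted p = 0.284 with an estimated correlation). Neat1 reached 1250 CPM in IM661 against 431 and 381 CPM in IM649 and IM650, and without IM661 its log2 fold change was 2.01 in place of 2.83. The list call ended without IM648 (adjusted p = 0.10), IM661 (0.0629), NCM648 (0.0571), NCM659 (0.0619), NCM649 (0.0515), NCM650 (0.0714) or NCM661 (0.0746). The share of reads outside exons was higher in these libraries too, at 65.2% against 42.0%. Kcnq1ot1 lies antisense within Kcnq1, and because the strand setting is not given, reads of the 2 genes cannot be told apart.

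Other genes that rose in IM deleted were Tbrg3 (6.82-fold, 66.6 ± 5.39 against 9.76 ± 3.43 CPM), Zfp488 (5.41-fold, 322 ± 75.2 against 59.5 ± 27.2 CPM), Dclre1c, the DNA end-joining nuclease Artemis (3.86-fold), and Slc5a3, a myo-inositol transporter (3.67-fold). Akap9, an anchoring protein of the Golgi and centrosome (3.51-fold, 401 ± 40.5 against 114 ± 49.5 CPM), Nktr (3.06-fold) and Ubn2 (2.88-fold) rose too. Adjusted p of these genes lay between 0.0444 and 0.0462. The 7 genes that fell encode abundant proteins of translation and the cytoskeleton. Among them were the ribosomal proteins Rps27 (2.63-fold, 90.3 ± 18.2 against 237 ± 13.8 CPM), Rpl37 (2.60-fold, 115 ± 12.6 against 299.8 ± 15.4 CPM) and Rpl26 (2.31-fold). The ribosome-bound scaffold Gnb2l1, also called Rack1 (2.57-fold), the elongation factor Eef1a1 (2.23-fold), beta-actin, Actb (2.29-fold, 3521 ± 728 against 8067 ± 815 CPM), and the GTPase Rhoa (2.04-fold, 356 ± 8.85 against 728 ± 30.4 CPM) completed the set. Adjusted p was 0.0444 or 0.0447. Several of these have many processed pseudogenes, so their counts are uncertain. Next in order were Sh3bgrl3, Eno1 (121 ± 34.4 against 287 ± 29.5 CPM) and Gapdh (161 ± 20.7 against 358 ± 27.9 CPM), each with an adjusted p of 0.0542, which did not pass.

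Glycolysis and mitochondrial genes were lower in IM deleted as lists. Glycolysis genes had a median of -0.60, none of 22 passed, and 5 fell when adjusted over the list alone (camera adjusted p = 2.70e-05). This is the only IM list whose call held with an estimated correlation (adjusted p = 0.0257), and fry gave 0.00245. Oxidative phosphorylation genes had a median of -0.82, with all 46 members below 0, 0 past the test and 2 lower over the list alone (adjusted p = 4.66e-12; adjusted p = 0.0850 with an estimated correlation; fry 0.0182). Atp5b, the catalytic subunit of ATP synthase, stood at 193 ± 16 against 391 ± 34.0 CPM (adjusted p = 0.0664). Hypoxia response genes outside glycolysis had a median of -0.26 and did not pass (adjusted p = 0.108). Ribosomal protein genes, a class not among the lists, had a median of -0.99 in IM, with all 81 members below 0 and 3 lower past the test. The share of reads outside exons separates the same libraries (65.2% against 42.0%).

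Macrophage genes were lower in IM deleted as well. Interstitial macrophage markers had a median of -0.69 with 31 of 37 below 0 (adjusted p = 1.51e-14; adjusted p = 0.0850 with an estimated correlation; fry 0.0403). No member passed. Sepp1, or selenoprotein P, stood at 1073 ± 180.2 against 2349 ± 229.5 CPM (adjusted p = 0.141). MHC class II genes, which present antigen, had a median of -0.90 (adjusted p = 1.78e-05; adjusted p = 0.303 with an estimated correlation). Cd74, the invariant chain, stood at 3916 ± 1640.3 against 7837 ± 1118 CPM (adjusted p = 0.237). Alveolar macrophage markers (median -0.55, adjusted p = 0.000118), classical monocyte markers (-0.38, 0.00105), alternative activation genes (-0.34, 0.00182) and nonclassical monocyte markers (-0.28, 0.0154) were lower as lists, with no member past the test. In that order the adjusted p was 0.284, 0.132, 0.466 and 0.755 with an estimated correlation. Beside random lists of like expression and exon length these 4 lay inside the 95% range, at the 14.8, 10.04, 27.3 and 28.3 percentile (18 of the 19 alveolar markers have a known length), whereas the interstitial macrophage and MHC class II lists lay below it, at the 0.58 and 0.39 percentile. The share of reads outside exons differed between the same libraries (65.2% against 42.0%).

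Inflammatory genes had a median of -0.29 in IM, nearer 0 than in NCM, and no member passed the test (adjusted p = 0.0474; adjusted p = 0.641 with an estimated correlation). Tnf stood at 172 ± 57.9 against 326 ± 84.8 CPM (adjusted p = 0.258) and Ccl3 at 163 ± 32.3 against 294 ± 70.3 CPM (adjusted p = 0.305). Immediate early genes (-0.34, adjusted p = 2.70e-05; adjusted p = 0.307 with an estimated correlation) and factors that act on vessels (-0.24, 0.0283; 0.544 with an estimated correlation) were lower as lists. Random lists matched on expression and exon length had a median of -0.49 beside the inflammatory list and -0.47 beside the immediate early genes, below those lists' own medians, and those beside the vessel factors placed that list at their 36.3 percentile. Sex-linked genes had a median of 0.85, with 2 of 5 higher when adjusted over the list alone (adjusted p = 0.0386; adjusted p = 0.284 with an estimated correlation). Ddx3y stood at 158 ± 26.4 against 87.5 ± 14.1 CPM (adjusted p = 0.226). Calls ended for the inflammatory list without IM648 (adjusted p = 0.377), IM649 (0.0526) or IM650 (0.393), and for the list of vessel factors without IM659 (0.0750). That of the sex-linked list ended without IM648 (0.0575), IM659 (0.0562) or IM661 (0.0533). Xist, the RNA of the inactive X chromosome, had at most 23 counts in any library.

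The other lists did not pass in IM. Their medians were -0.13 for interferon response genes (adjusted p = 0.533), 0.14 for dendritic cell markers (0.735) and 0.23 for T and NK cell markers (0.735; median 0.12 with 3 members at the floor). They were 0.10 for B cell markers (0.798), 0.22 for neutrophil markers (0.735), 0.15 for endothelial markers (0.735), 0.10 for fibroblast and smooth muscle markers (0.735) and -1.14 for erythroid and platelet markers (0.735). For epithelial markers the median (0.05) and mean (0.10) lay above 0 while camera ranked them below other genes (adjusted p = 0.434). For cell cycle genes the median (-0.19) and mean (0.03) differed in sign (adjusted p = 0.735). In all, 41 genes passed in IM, 34 higher and 7 lower, and 14 of those higher have only systematic names. The lists past the threshold were 13, 2 higher and 11 lower, 4 of them with fry.

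All 41 calls lie close to the threshold, with a smallest adjusted p of 0.0444. In edgeR 0 genes passed with sequencing lane or the share of non-exonic reads as a covariate, 1 without composition factors and 950 when only the 6 IM libraries were fitted. With the non-exonic share the median log2 fold change of the 34 higher genes went from 2.01 to 0.95 (median standard error 0.38 and 0.47) and that of the 7 lower genes from -1.21 to -1.05 (0.22 and 0.36). That share separates the genotypes in IM without overlap, so the 2 cannot be set apart there. DESeq2 called 373. Leaving out 1 library gave 0 genes (each of IM648, IM659, IM660, NCM657 and NCM659), 1, 1 and 2 (IM649, IM650 and IM661), 8 (NCM648), 115 (NCM649) and 234 (NCM661).

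Whether the deletion went with a different change in IM than in NCM was tested as the difference of the 2 effects, IM minus NCM. No gene passed this test in edgeR, where the smallest adjusted p was 0.139; 1271 genes had an unadjusted p under 0.05, DESeq2 called 62 and limma with sample weights 7. The gene with the smallest p was C5ar1, with a difference of 2.24 log2 units (adjusted p = 0.139), followed among genes higher in this difference by Ifrd1 (2.37), Plcl2 (1.88), Jmjd1c (1.71) and Jarid2 (1.94). Genes lower in it were F2r, a thrombin receptor (-3.72), Ephx1 (-2.74), Cd34 (-2.43), Cav2 (-2.41) and Nes (-2.13). For Hif1a the difference was 0.18 (adjusted p = 0.921) and for Cx3cr1 -0.14 (adjusted p = 0.977); both signs change when single libraries are left out (-0.05 without IM659 for Hif1a, 0.36 without NCM649 for Cx3cr1). The median difference of all genes was 0.19, or 0.04 with DESeq2's factors, so values are relative to that shift.

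Of the 24 lists 6 differed between the cell types. Inflammatory genes had a median difference of 1.2, 11 of 28 positive past the test when adjusted over the list alone (camera adjusted p = 0.000166; adjusted p = 0.632 with an estimated correlation), which followed their lower level in NCM deleted. Negative differences were those of endothelial markers (median -1.80, adjusted p = 1.43e-12), epithelial markers (-0.76, 0.000135), alveolar macrophage markers (-0.87, 0.00154), fibroblast and smooth muscle markers (-0.55, 0.0238) and oxidative phosphorylation genes (-0.31, 0.0130). In that order the adjusted p was 0.632, 0.632, 0.632, 0.813 and 0.714 with an estimated correlation. Glycolysis genes did not pass this test, with a median of 0.17 although camera ranked them below other genes (adjusted p = 0.972). The same held for interferon response genes (0.16), alternative activation genes (0.59), factors that act on vessels (0.20), interstitial macrophage markers (0.28) and classical monocyte markers (0.32). For MHC class II genes the median (0.02) and mean (-0.74) differed in sign. Adjusted p of these lists lay between 0.0904 and 0.972. Only Actb and Gnb2l1 passed the test as lower in both cell types, where independent lists would share 0.0236 genes, and none passed as higher in both. Without NCM661 the interaction gave 34 genes and 3 lists, and without NCM649 1 gene. The calls of the inflammatory (adjusted p = 0.0895), oxidative phosphorylation (0.159) and fibroblast lists (0.145) ended without NCM661. That of the oxidative phosphorylation list also ended without IM650 (0.0557), and that of the fibroblast list without IM659 (0.198), IM661 (0.0943), NCM648 (0.0589) or NCM650 (0.137).

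Comparison of IM control with NCM control describes how the sorted cell types differ when Hif1a is intact, with IM given first. Genes of tissue macrophages were higher in IM. Ms4a7 (chromosome 19, 11321039 to 11336146) was 40.8-fold higher (126 ± 18.8 against 3.06 ± 0.716 CPM, adjusted p = 0.000438). The lectin Mgl2 (39.1-fold), the glycoprotein Gpnmb (40.5-fold), Fcrls (32.5-fold) and Cd72 (26.2-fold) were higher too. So were Rab3il1 (26.4-fold), Col14a1 (25.1-fold), Zmynd15 (24.2-fold), the organic anion transporter Slco2b1 (23.9-fold) and the proton pump subunit Atp6v0d2 (19.6-fold). Nonclassical monocyte genes were lower in IM. Emr4, an adhesion receptor (chromosome 17, 55749984 to 55853662), was 106-fold lower (6.55 ± 3.91 against 692 ± 279.8 CPM, adjusted p = 0.000537). Lower as well were Treml4 (85.8-fold), Itgal, the alpha chain of the integrin LFA-1 (23.9-fold, 68.1 ± 16.3 against 1627 ± 540.2 CPM), Ceacam1 (23.1-fold) and Cyfip2 (62.8-fold). Ccdc88c (67.2-fold), Setbp1 (47.6-fold), the enolase gene Eno3 (29.2-fold), Mdm1 (25.5-fold) and Ldlrad3 (25.1-fold) completed them. Adjusted p for these genes lay between 2.26e-05 (Cyfip2) and 0.0291 (Gpnmb). Some folds rest on single libraries. Without NCM659 the log2 fold change was 9.29 for Gpnmb (5.34 with it), 6.87 for Fcrls (5.02), 5.89 for Cd72 (4.71), 5.35 for Rab3il1 (4.72), 5.44 for Slco2b1 (4.58) and 4.88 for Atp6v0d2 (4.29). It was -6.22 for Setbp1 without IM659 (-5.57) and -7.24 for Treml4 without IM648 (-6.42). All 1066 calls, 401 higher and 665 lower, come from libraries whose lanes differ by cell type.

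Marker lists differed between the control groups. Of the interstitial macrophage markers 26 of 37 were higher in IM control, 32 when adjusted over the list alone, with a median of 2.83 (adjusted p = 2.32e-31). This was the only list here past the threshold with an estimated correlation (adjusted p = 0.0292). The mannose receptor gene Mrc1 stood at 1941 ± 166 against 118 ± 77.8 CPM. Of the nonclassical monocyte markers 25 of 33 were lower, 27 over the list alone, with a median of -3.15 (adjusted p = 2.74e-23; adjusted p = 0.103 with an estimated correlation). MHC class II genes had a median of 2.90, with 7 of 11 higher and 8 over the list alone (adjusted p = 4.25e-11; adjusted p = 0.135 with an estimated correlation). Cd74 stood at 7837 ± 1118 against 913 ± 388 CPM. Alternative activation genes had a median of 3.03, with 14 of 25 higher and 17 over the list alone (adjusted p = 2.84e-15; adjusted p = 0.0883 with an estimated correlation). Alveolar macrophage markers had a median of 3.70, 9 higher and 1 lower of 19, or 13 and 1 over the list alone (adjusted p = 3.04e-11; adjusted p = 0.0883 with an estimated correlation). Chi3l3, a chitinase-like protein, stood at 1246 ± 52.0 against 95.8 ± 35.3 CPM.

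Inflammatory and immediate early genes were higher in IM control. Of the inflammatory genes 7 of 28 were higher and 1 lower, or 15 and 1 over the list alone. Their median was 1.46 (adjusted p = 1.06e-07; adjusted p = 0.151 with an estimated correlation). Tnf stood at 326 ± 84.8 against 104 ± 13.1 CPM and Ccl2 at 236 ± 53.4 against 20.8 ± 15.0 CPM. Of 28 immediate early genes 9 were higher and 3 lower, or 11 and 3 over the list alone. Their median was 0.74 (adjusted p = 1.24e-06; adjusted p = 0.25 with an estimated correlation), with Fos at 2061 ± 549 against 575 ± 84.5 CPM and Klf4 at 184 ± 28.8 against 400.1 ± 36.4 CPM. Higher as lists were factors that act on vessels (7 higher and 1 lower of 38, median 0.91, adjusted p = 0.000338), cell cycle genes (1 higher and 1 lower of 31, 1.30, 0.000424) and oxidative phosphorylation genes (none past, 0.41, 0.0213). In that order the adjusted p was 0.25, 0.435 and 0.509 with an estimated correlation. The call of the last ended without NCM659 (adjusted p = 0.0506). Glycolysis genes had a median of -0.02 (adjusted p = 0.969), with Slc16a3, a lactate exporter, lower in IM (12.3-fold, 9.43 ± 2.42 against 116 ± 20.9 CPM). Nuclear RNAs had a median of 0.31, -0.57 with 2 members at the floor, while camera ranked them below other genes (adjusted p = 0.80). Neat1 (2.72-fold) and Malat1 (2.1-fold) were lower in IM control, whose share of reads outside exons was also the lowest. The cytotoxic gene Gzma had no count in IM control and stood at 34.3 ± 19.8 CPM in NCM control.

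The other lists did not pass between the control groups. Medians were 0.02 for hypoxia response genes (adjusted p = 0.978), 0.01 for interferon response genes (0.557), 0.03 for dendritic cell markers (0.80), -1.83 for T and NK cell markers (0.130) and -1.08 for B cell markers (0.543). They were -0.40 for neutrophil markers (0.455), 0.35 for endothelial markers (0.543) and 0.30 for epithelial markers (0.581). For the rest they were 0.40 for fibroblast and smooth muscle markers (0.515), -0.50 for erythroid and platelet markers (0.938) and -0.74 for sex-linked genes (0.0821). For classical monocyte markers the median (-0.08) lay below 0 while camera ranked them above other genes (adjusted p = 0.317). Of their members 3 were higher and 1, Plac8, lower. The count fell to 28 genes with the share of non-exonic reads as a covariate and was 2015 with only the 6 control libraries fitted and 1768 with DESeq2. It was 504, 528 and 599 without IM648, IM659 and IM660 and 533 without NCM648.

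Comparison of IM deleted with NCM deleted gave the same kind of difference after deletion of Hif1a, with IM first. The growth factor gene Igf1 was 95-fold higher in IM (275 ± 52.4 against 2.75 ± 2.5 CPM, adjusted p = 0.000771). Higher as well were the complement genes C1qa (35.7-fold), C1qc (34.2-fold) and C3ar1 (51.4-fold) and the chemokine Cxcl16 (43.1-fold, 677 ± 348 against 15.6 ± 6.76 CPM, adjusted p = 1.87e-05). So were Slco2b1 (89.0-fold), Il1rn, which encodes the interleukin-1 receptor antagonist (33.8-fold), F13a1 (32.6-fold), the scavenger receptor Stab1 (31.9-fold) and the adhesion molecule Vcam1 (31.9-fold). Lower in IM were Emr4 (81.9-fold), Treml4 (55.8-fold), Mdm1 (21.1-fold), Cyfip2 (19.5-fold), Setbp1 (19.4-fold), Itgal (17.1-fold, 49.6 ± 3.26 against 851 ± 442 CPM), Dnahc12 (15.7-fold), Ccdc88c (13.8-fold) and Rasgrp2 (13.2-fold). Single libraries moved some of these log2 fold changes. Without NCM661 they were 9.10 for Slco2b1 (6.48 with it), 7.30 for Igf1 (6.57), 7.06 for C3ar1 (5.68) and 5.69 for Vcam1 (4.99). They were 6.17 for F13a1 without NCM649 (5.03), 5.99 for C1qa without NCM650 (5.16) and 4.82 for Cxcl16 without IM661 (5.43). Without IM649 they were -7.50 for Emr4 (-6.36) and -6.43 for Treml4 (-5.80), and without IM650 -4.89 for Setbp1 (-4.28). In all, 652 genes passed, 459 higher and 193 lower. Of all genes 241 were higher and 166 lower in both comparisons of cell types, where independent lists would share 12.9 and 9.0. The median of all genes was 0.14, or 0.03 without composition factors.

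Inflammatory genes separated the deleted cell types. In IM 15 of 28 were higher, 22 over the list alone, with a median of 2.43 (adjusted p = 1.60e-14; adjusted p = 0.0896 with an estimated correlation). Among them were Tnf (14.1-fold), Cxcl2 (21.8-fold, 594 ± 162 against 27.3 ± 14.2 CPM) and Ccl3 (5.80-fold). Interstitial macrophage markers had a median of 3.25, with 25 of 37 higher and 32 over the list alone (adjusted p = 4.92e-25; adjusted p = 0.0588 with an estimated correlation). Alternative activation genes (10 of 25 higher, 19 over the list alone, median 3.25, adjusted p = 1.60e-14) and MHC class II genes (7 of 11, 7 over the list alone, 2.67, 2.91e-07) were higher in IM. In that order the adjusted p was 0.0896 and 0.215 with an estimated correlation. Nonclassical monocyte markers had a median of -2.36 (adjusted p = 2.30e-20; adjusted p = 0.139 with an estimated correlation). Of them 23 of 33 were lower and 1 higher, or 25 and 2 over the list alone. Endothelial markers had a median of -1.35, all 19 below 0 and none past the test (adjusted p = 2.56e-13; adjusted p = 0.215 with an estimated correlation). Epithelial markers had a median of -0.67 with 1 lower, Napsa (adjusted p = 0.000305; adjusted p = 0.434 with an estimated correlation). Immediate early genes were higher in IM, 10 of 28 past the test, or 15 higher and 1 lower over the list alone (median 0.95, adjusted p = 2.91e-07). Cell cycle genes (1 higher, Mki67, 3 over the list alone, 1.83, 9.15e-07) and alveolar macrophage markers (4 higher and 1, Pparg, lower, 2.37, 1.44e-06) followed. For factors that act on vessels the median was 1.05, with 7 higher and 1 lower (adjusted p = 0.0196). In the order given the adjusted p of these 4 lists was 0.215, 0.219, 0.213 and 0.472 with an estimated correlation. The epithelial call ended without IM661 (adjusted p = 0.209) and that of vessel factors without NCM661 (0.108). Of these 11 lists 0 held with an estimated correlation and 9 of the 24 passed with fry.

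The other lists did not pass between the deleted groups, with medians of 0.03 for glycolysis (adjusted p = 0.941), -0.15 for hypoxia response genes (0.0729), 0.04 for oxidative phosphorylation (0.611) and 0.43 for interferon response genes (0.611). Medians of marker lists were 0.14 for classical monocyte markers (0.611), 0.20 for dendritic cell markers (0.941), -0.99 for T and NK cell markers (0.941; -0.88 with 1 member at the floor), and -0.54 for B cell markers (0.941). They were -0.36 for fibroblast and smooth muscle markers (0.0959), -0.91 for erythroid and platelet markers (0.972), -0.06 for sex-linked genes (0.941) and 0.93 for nuclear RNAs (0.296). For neutrophil markers the median (-0.02, -0.12 with 2 members at the floor) and mean (1.34) differed in sign (adjusted p = 0.941). Glycolysis, oxidative phosphorylation, dendritic cell and sex-linked genes were ranked below other genes by camera although their means lay above 0. The count was 228 with only the 6 deleted libraries fitted and 1228 with DESeq2, and it was 391 and 346 without IM649 and IM661 and 1709 without NCM661.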

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

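The tests of handling, RNA composition, cell shares, carry-over, genomic DNA and other hypoxia genes given here, their repeats without each library, and the random lists they use were chosen after the results they bear on were seen. The proteasome test uses those lists too but was set before the values of its own genes were seen, and the splits within the 5 designed comparisons were fixed before their counts were seen.

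Of the gene lists 6 stood out because their genotype effect differed between IM and NCM in the test of the difference itself. The adjusted p was 1.43e-12 for endothelial markers, 0.000135 for epithelial markers, 0.000166 for inflammatory cytokine genes, 0.00154 for alveolar macrophage markers, 0.0130 for oxidative phosphorylation genes and 0.0238 for fibroblast and smooth muscle markers. With an estimated correlation 0 of them passed. Chance cannot be excluded for the number of such lists: 61 of 100 splits of the genotype labels within cell types gave at least the real 6, the highest other giving 15. For genes the real difference gave 0, all 100 splits gave as many, and the highest other gave 368. That split exchanges the labels of the NCM libraries alone, so its count is the summed genotype effect of both cell types, a structure of these samples. Without NCM661 the real counts were 34 genes and 3 lists.

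A signal also lay in reads that the comparisons of genes do not use. The mean share of reads outside annotated exons was 65.2% in IM deleted, above the 42.0% of IM control. Genomic DNA was examined as its source with 1452 olfactory and vomeronasal receptor rows, most of which had no read. In the IM deleted libraries 34 to 43 of these rows had a read (at most 2.96%), and in the IM control libraries 16 to 32 (at most 2.20%). The NCM libraries went both ways. NCM649 and NCM650, with the highest shares outside exons, had a read in 5 and 7 rows and NCM661 in 33, against 9 to 15 rows in NCM control. The reads on these rows do not bear on even coverage by DNA, because a single row held 380 to 492 of 921 to 1291 reads in the IM control libraries, 715 to 1052 of 1778 to 2369 in the IM deleted and 580 to 1090 of 1364 to 2143 in the NCM libraries. Shares of rows stayed far below the 10% set for this test, which assumes even coverage and was chosen after the data were seen. In IM the number of rows with a read rose without overlap, so genomic DNA cannot be told apart from RNA outside exons. The reads themselves were not held, so introns, intergenic sequence and antisense reads on exons could not be separated.

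The first pattern weighed is that glycolysis genes were lower in the deleted libraries of both cell types (medians -0.60 in IM and -0.59 in NCM). In IM a shift in RNA composition with expression and exon length is argued against as the whole cause, since the median of the 21 members of known length (-0.59) lay at the 0.01 percentile of matched random lists and below their 2.5% bound without each single library too. This position is not particular to glycolysis. In IM oxidative phosphorylation genes lay at the 0.01 percentile and ribosomal protein genes at the 0 percentile of their matched lists. In NCM a shift with expression and exon length cannot be told apart, as the glycolysis percentile of 0.5 became 8.42 without NCM650 and 4.41 without NCM657. A lower share of short mature mRNA of housekeeping genes cannot be told apart either. The prediction set beforehand for it, a proteasome median below the 2.5% bound of matched random lists in IM, was met narrowly. The 39 proteasome subunit genes had a median of -0.53 beside a bound of -0.52 (1.73 percentile). In NCM, which the prediction did not name, they lay at the 42.4 percentile. These lists were matched on exon length, so they do not test length itself. Genomic DNA cannot be told apart either (2.96% above). Loss of Hif1a and Cre itself stay open, as hypoxia response genes outside glycolysis lay at the 6.08 percentile of matched lists in IM and at the 79.3 percentile in NCM.

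The second pattern is that inflammatory genes were lower in NCM deleted (median -1.25, bootstrap interval -1.69 to -0.78). A shift in RNA composition with expression and exon length is argued against, since matched random lists had a median of -0.36 with a 95% range of -0.71 to -0.01, and the list stayed below the range without each single library. A handling or stress response cannot be told apart, because the median differed by -0.52 (interval -1.04 to -0.05) from the -0.73 of immediate early genes not on the inflammatory list, but by -0.07 without NCM661 (interval -0.82 to 0.22) and by -0.21 without NCM657 (-0.91 to 0.08). A lower share of monocyte RNA cannot be told apart from a specific loss, because the difference from nonclassical monocyte markers was -0.40 with an interval of -0.82 to 0.09. Without NCM661 the inflammatory median was -0.89 and the marker median -0.52, and a specific effect of the deletion remains a hypothesis.

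The third pattern is that endothelial transcripts were higher in NCM deleted (median 1.85, interval 1.74 to 2.0; 1.17 without NCM661). A lower share of monocytes alone would raise the markers of all other cells alike, and it cannot be told apart. Endothelial markers exceeded T and NK cell markers by 2.33 (interval 1.5 to 3.22), and by at least 1.92 when any library was left out (NCM657, interval 0.79 to 3.23). But the T and NK medians were low, from 0 (NCM649) to 9.30 CPM (NCM657) in the NCM libraries. Endothelial markers exceeded epithelial markers by 0.94 (interval 0.15 to 1.34). That interval included 0 without NCM657 (-0.10 to 1.38) or NCM661 (-0.17 to 1.11). A shift in RNA composition with expression and exon length is argued against, since matched random lists had a median of -0.27 (range -0.57 to 0.07), and the endothelial list stayed above the range without each single library. Carry-over of endothelial RNA or cells cannot be told apart from a change in the sorted cells, because all 19 measured members were positive but their signs were known when this test was chosen. The labels give no gate that would remove endothelial cells, and whether lung endothelium differs between the genotypes was not tested.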

How the results depend on the processing

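Total-count scaling, the non-exonic share as a covariate, cyclic loess and every result for the averaged genotype effect were chosen after the data were seen; the other settings were fixed earlier. The cause of the changes was not tested. Counts below are genes past the threshold, beside 41 (IM), 60 (NCM), 0 (difference of effects), 1066 (control groups), 652 (deleted groups) and 368 (averaged effect).

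Filters and gene sets changed the genotype counts. With no low-count filter 77 genes passed in IM and 153 in NCM, and with a minimum count of 30 the counts were 0 and 11. Without ribosomal RNA, mitochondrial, haemoglobin and sex-linked rows 3 passed in IM. When only the libraries compared were fitted, 950 passed in IM, 0 in NCM, 2015 between the control groups and 228 between the deleted groups, and Cx3cr1 was past the threshold between the control groups at 0.85.

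Covariates and scaling lowered most counts. Lane as a covariate gave 0 in IM, 3 in NCM and 98 for the averaged effect, and total-count scaling gave 1, 4 and 245. The non-exonic share as a covariate gave 0 in IM, 351 in NCM, 28 between the control groups and 31 for the averaged effect. That covariate turned the sign of H2-DMa (0.059) and Csf3r (-0.92) in IM, of Hif1a in the difference of effects (-0.094), and of Eng (-0.051), Col3a1 (-0.70) and Ppbp (-4.55) between the control groups. None of these signs had passed a test.

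Other tools moved the counts both ways. DESeq2 gave 373, 953, 62, 1768, 1228 and 1138 genes in the order above. Limma-voom with sample weights gave 2203, 1, 7, 2667, 345 and 796, and with it Cx3cr1 passed in IM (-1.19), between the control groups (0.94) and in the averaged effect (-1.14). After cyclic loess 159 passed in IM and 2 in NCM, Cx3cr1 passed between the control groups (1.14), Hif1a turned sign in the difference of effects (-0.17) and Xist between the deleted groups (-1.57).

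Residuals showed no pairing by the numbers in the titles. Their correlations between the cell types were 0.02, 0.08, 0.01, -0.05 and -0.07 for the 5 numbers found in both, and the random block correlation was -0.01. Low correlations between different cell types cannot show that equal numbers stand for different animals. With the number as a random block in limma-voom 181 genes passed in IM and 196 in NCM, where the tool changed as well, so these counts do not show an effect of the block. With it as a fixed block in edgeR 315 passed between the control groups and 405 between the deleted groups, from the 10 libraries whose numbers occur in both cell types. Cx3cr1 passed in the averaged effect (-1.10), and Hif1a (-0.028) and Gp9 (0.037) turned sign between the control groups.

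Lists past the threshold depended on the correlation between genes. With an estimated correlation 1 passed in IM, 0 in NCM, 0 in the difference of effects, 1 between the control groups, 0 between the deleted groups and 1 in the averaged effect, beside 13, 8, 6, 10, 11 and 11. With fry 4 passed in IM, 1 in NCM, 0 in the difference of effects and 6 in the averaged effect.

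Leaving out each library in turn gave 0 to 234 genes in IM, 4 to 570 in NCM, 0 to 34 in the difference of effects, 504 to 1525 between the control groups, 346 to 1709 between the deleted groups and 68 to 1002 in the averaged effect. The highest count came without NCM661, except between the control groups, where it came without NCM649. Lists ranged from 10 to 14, 6 to 15, 3 to 9, 10 to 12, 10 to 13 and 8 to 13. Hif1a ranged from -0.32 to -0.16 in IM, -0.57 to -0.28 in NCM, -0.046 to 0.33 in the difference of effects, -0.030 to 0.15 between the control groups, 0.09 to 0.38 between the deleted groups and -0.40 to -0.25 in the averaged effect. Cx3cr1 ranged from -1.43 to -0.74, -1.37 to -0.45, -0.70 to 0.36, 0.69 to 1.15, 0.19 to 1.23 and -1.19 to -0.71 in the same order. Flt1 in IM ranged from -0.043 to 0.86, Ppbp in NCM from -8.28 to 0.30 and Eif2s3y in NCM from -0.70 to 0.074.

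RLE factors and thinning changed none of the counts by more than 1.5 times. Of the values of lists and of single named genes other than Hif1a and Cx3cr1 under all settings, 6766 stayed the same in sign and call, 187 gained a call, 1092 lost one and 10 turned sign. Hif1a and Cx3cr1 turned sign in 9 further values, all of them in the difference of effects or between the control groups.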

Other observations

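The genotype effect averaged over both cell types, its splits, the matched random lists, the counts of genes without overlap and the covariate of non-exonic reads were chosen after the results had been seen, whereas the splits of the designed comparisons were fixed earlier.

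Averaged over IM and NCM, the deletion went with more calls than in either cell type alone. C5ar1 was 3.75-fold lower on average (IM 188 ± 15.2 against 325 ± 14 CPM, NCM 14.3 ± 3.28 against 116 ± 21.2 CPM, adjusted p = 0.000209). Tnf was 4.02-fold lower (IM 172 ± 57.9 against 326 ± 84.8, NCM 12.3 ± 3.98 against 104 ± 13.1, adjusted p = 0.00129). Unc119 (3.63-fold, adjusted p = 0.0172), Ccl4 (6.15-fold, 0.0182) and Ms4a6d (3.59-fold, 0.0256) were lower too. Shroom3 was 5.64-fold higher (IM 47.4 ± 32.1 against 11.5 ± 2.74, NCM 97.3 ± 30 against 12.6 ± 6.72, adjusted p = 0.00735), as were Nckap5 (5.10-fold, 0.00876), Phldb2 (4.91-fold, 0.0135), Fam196a (4.81-fold, 0.0153) and Hmcn1 (4.57-fold, 0.0346). Ccl4, Shroom3, Nckap5, Phldb2 and Hmcn1 did not separate the genotypes without overlap in both cell types. Of the list members, Gapdh (2.40-fold), Eno1 (2.71-fold) and Gpi1 (2.03-fold) of glycolysis, Ccl3 (3.06-fold) and Nfkbia (2.23-fold) were lower, and Neat1 (3.12-fold), Kcnq1ot1 (3.59-fold) and Malat1 (1.99-fold) higher. Nfkbia, Neat1 and Malat1 did not separate the genotypes without overlap in both cell types either. The log2 fold change was 2.83 in IM and 0.45 in NCM for Neat1, and 1.68 and 0.32 for Malat1. Without NCM661 the averaged log2 fold change of Ccl4 was -3.47 in place of -2.62. For Hif1a the averaged log2 fold change was -0.29 (adjusted p = 0.342), and for Cx3cr1 it was -0.91 (adjusted p = 0.126).

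In edgeR 368 genes passed in the averaged effect, 122 higher and 246 lower. Only the real split (1 of 100) gave as many, and the highest other gave 4. These splits do not exclude chance, because the contrast was chosen after the results had been seen. They also exchanged labels in each cell type separately, although equal numbers may stand for the same animal. Over all 14254 genes 501 were lower and 157 higher with no overlap between the genotypes in either cell type (3.51 and 1.10%). Chance gives 0.25% per direction if the cell types are independent. The split between higher and lower depends on the scaling: RLE factors gave 165 higher and 181 lower, and total-count scaling 118 and 127. With lane as a covariate 98 genes passed and with the share of non-exonic reads 31, of which 12 were among the 368. With that share as a covariate the median log2 fold change of the 122 higher genes went from 1.47 to 1.23 and that of the 246 lower genes from -1.0 to -0.89. Their median standard errors rose from 0.31 to 0.45 and from 0.20 to 0.30. In IM the share separates the genotypes without overlap, so the calls lost this way do not test RNA composition as a cause. Leaving out 1 library gave 133, 144 and 139 genes (IM648, IM659, IM660), 105 and 68 (IM649, IM650), 129 (NCM657), 555 (NCM649) and 1002 (NCM661). On simulated data this contrast recovered 72% of genes changed 4-fold and 16% of those changed 2-fold.

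In the averaged effect 11 lists passed, 3 higher and 8 lower, and chance cannot be excluded for that number, as 14 of 100 splits gave as many and the highest other gave 15. Glycolysis (median -0.58, 3 of 22 lower, adjusted p = 3.20e-06) is the list that held with an estimated correlation (adjusted p = 0.0139). Lower without holding were oxidative phosphorylation (-0.70), inflammatory genes (-0.69), interstitial macrophage (-0.83), nonclassical monocyte (-0.52) and classical monocyte markers (-0.66), MHC class II (-0.89) and immediate early genes (-0.43). Higher were endothelial markers (1.0), fibroblast and smooth muscle markers (0.51) and nuclear RNAs (1.64), with estimated-correlation adjusted p between 0.259 and 0.738. These averages hide unequal parts: endothelial markers had a median of 0.15 in IM (adjusted p = 0.735) and 1.85 in NCM, fibroblast and smooth muscle markers 0.10 (0.735) and 0.89, and inflammatory genes -0.29 and -1.25, with the differences given above. Nuclear RNAs had 1.68 in IM and 0.45 in NCM (adjusted p = 0.312), a difference that did not pass (adjusted p = 0.264). Of these calls, those of classical monocyte markers ended without NCM661 (adjusted p = 0.118) and of MHC class II genes without NCM657 (0.124) or NCM650 (0.115). The fibroblast call ended without 8 single libraries and the nuclear RNA call without 7.

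Ribosomal protein genes had a median of -0.99 in IM, with 81 of 81 below 0, and of -0.87 in NCM, with 79 below 0, and 3 passed in each. Random lists matched on expression and exon length in IM had a median of -0.54 beside this class. Across 13777 genes the log2 fold change rose with exon length (Spearman correlation 0.262 in IM and 0.160 in NCM). Proteasome genes had a median of -0.53 in IM and -0.30 in NCM (42.4 percentile of matched lists). Near-identical copies make counts of ribosomal protein genes uncertain, and the counts hold no measure of RNA integrity.

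The numbers of genes past the threshold in the designed comparisons were set beside other splits of the same 6 libraries. In IM the real split gave 41 genes and the highest other 0, in NCM 60 and 51, between the control groups 1066 and 0, and between the deleted groups 652 and 0. In each of them only 1 split of 10, the real one, gave as many. For lists the values were 13 and 16 in IM, 8 and 9 in NCM, 10 and 12 between the control groups and 11 and 11 between the deleted groups, with 2, 3, 4 and 2 of 10 splits giving as many. With 10 splits these are too few for a share under 0.05. The NCM split with 51 genes sets NCM649 and NCM650 and NCM648 apart, the NCM libraries with the 3 highest shares of non-exonic reads (72.7, 71.9 and 66.8%).

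Of single libraries NCM661 and NCM649 stood apart. NCM649 had the lowest sample weight (0.261, against 0.412 in NCM661), the fewest genes with a count (10526), a first principal component of 225 and correlations with NCM650 and NCM661 of 0.740 and 0.778, where those 2 correlated at 0.809. NCM661 had 17179 genes with a count, against 11933 in NCM650, a share of non-exonic reads of 55.1% against 72.7 and 71.9% in NCM649 and NCM650, and a first principal component of -26.12 on the side of the IM libraries. Its interstitial macrophage markers were not higher (median 20.9 CPM, against 43.7 in NCM649 and 41.7 in NCM650). Its endothelial median was 326 CPM, against 137 and 174 CPM, and its nonclassical monocyte median 90.5 CPM, against 198 and 252 CPM. Without NCM661 570 genes passed in NCM, with all 60 calls among them, and Cx3cr1, at 46.9 CPM in it, had a log2 fold change of -0.45. Why these libraries differ was not tested.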
